A study of Ichthyophis bannanicus with 29 samples.

How the data were processed

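RNA was sequenced from 10 tissues of *Ichthyophis bannanicus* in 29 libraries, 3 per tissue except ovary with 2. Per the labels' protocols, messenger RNA was selected with poly-T oligonucleotides and libraries were made with the NEBNext Ultra RNA kit. The authors deposited 1 table of TPM, per the file headers, with 1 column per library and 53113 genes, and every column sums to 1000000. The gene IDs have the form that the Trinity assembler gives, in 46150 assembly components, per the row names of the deposited table. Such an assembled gene can be a fragment of a gene or join near-identical copies, so counts of genes here are counts of assembled sequences, and paralogs remain uncertain. The aligner, the quantifier, their versions and any filter before deposit are not given in the sources used here. TPM keeps no depth, so count tests and counting intervals were not used. Tissue and replicate number came from the sample labels, and all 29 columns matched a sample by name. The highest r between any 2 libraries was 0.945. The number of genes with exactly equal values above 0 was 0 for every pair, so each library was counted once.

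Values were read as deposited and 49 genes listed at 0 in every library were kept in the counts of the table. Genes at 1 TPM or more in at least 2 libraries, 50365 in number, were tested on log2(TPM + 1) with limma 3.58.1 in R 4.3.3. A model with a mean per tissue was fitted over all 29 libraries with an intensity trend in the empirical Bayes step. The contrasts were each tissue against the unweighted mean of the other 9, testis against ovary, skin against lung and blood against spleen. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, adjusted within each contrast, and a log2 difference of 1 or more in size. The correlation of libraries used a one-sided permutation test with 100000 shuffles of the tissue labels. Tau was computed on log2(mean TPM + 1) over the 10 tissue means for genes whose highest mean was 1 TPM or more. Other work used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

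Groups, the tests between tissues and most alternatives were fixed before the data were examined. Chosen after seeing the data were leaving out kidney replicate 1, testis replicate 1 and liver replicate 2 together, counting tau genes present in every library of their tissue, reading genes restricted to a tissue in other libraries, the counts of genes shared by 2 tissues or found in 1 library, the shuffles of replicate numbers, and reading kidney genes in the other tissues without testis replicate 1. Tests of explanations were set after the patterns were seen and before the value that decides each was known, except that of exchanged labels between kidney replicate 1 and ovary replicate 1, which was set after. Alternatives were a pseudocount of 0.1, no filter on low values, TPM rescaled by median-of-ratios factors, the replicate number as a block, each library left out in turn, only the libraries of the tissues compared, Spearman correlation, and other settings of tau. Weighting of libraries by limma's arrayWeights was tried after seeing the data, did not converge and was not used. The rule for named genes was the largest log2 differences among called genes whose libraries did not overlap. It was written for genes with names, and as the table pairs none with its IDs it was applied to IDs, at most 2 per direction of a comparison. The 35 marker and pathway lists, with 974 symbols, matched 0 genes, so tests of lists (camera) and of marker genes of cell types were not run. The step that calls genes was tested on simulated data for 50365 genes with 50 genes changed at each size. For kidney against the other tissues, it recovered 6% of genes changed 2-fold, 74% at 4-fold, 90% at 8-fold and 96% at 16-fold, with 6 false calls. For ovary it recovered 4%, 54%, 86% and 90%, with 9 false calls, and for testis against ovary 2%, 26%, 64% and 84%, with 1 false call. In the simulation all other genes had the same mean in every tissue, and genes varied independently without shifts of whole libraries. Many more genes were called in the data, so recovery and false calls there can differ. Genes changed 2-fold lay on the log2 limit of 1. No gene coordinates are given, since no genome was used here.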

Results

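Messenger RNA was measured by RNA sequencing in 10 tissues of *Ichthyophis bannanicus*, a caecilian, which is a limbless burrowing amphibian. Blood, heart, kidney, liver, lung, skin, spleen, stomach and testis had 3 libraries each, and ovary had 2 (replicates 1 and 3), which gave 29 libraries. The values were transcripts per 1000000 (TPM) for 53113 assembled genes, each known by an assembly ID, and the table pairs no gene names with the IDs. At most 2 IDs per direction are therefore printed for a comparison, as markers of the measurement and without a function. TPM sums to 1000000 in every library and keeps no sequencing depth, so the depth behind each value is unknown and no counting interval is given. The labels do not say whether the libraries of a tissue came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

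The tissues differed in how many genes reached 1 TPM and in how much of the RNA a few genes took. Counts at 1 TPM depend on the unknown depth and on the share that abundant genes take. They are therefore not counts of the genes that a tissue uses. On average kidney had the most genes at 1 TPM or more, 35689 ± 106 (SD, n = 3), and testis had 33754 ± 2698 (SD, n = 3). The highest single library was testis replicate 1 at 36057, which carried genes restricted to kidney. Stomach had 24837 ± 1835 and spleen 25638 ± 6312 (SD, n = 3 each), where spleen replicate 1 was the lowest of the 29 libraries at 18410. Spleen replicate 1 also had the lowest median-of-ratios factor, 0.473. In blood the 10 most abundant genes of each library took 50.9% ± 5.12 of all TPM (SD, n = 3), against 39.3% ± 4.72 in stomach and 13.1% ± 2.17 in testis (SD, n = 3 each). By tissue mean, the gene TRINITY_DN132001_c0_g1 was the most abundant one in 7 of the 10 tissues and held 16.4% ± 3.87 of TPM in blood (SD, n = 3). It did not lead in every library of liver and testis. Skin, spleen and stomach each had another most abundant gene. At the other end, 10028 genes were at 1 TPM or more in every library.

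Libraries grouped by tissue. The mean Pearson r of log2(TPM + 1) across genes was 0.866 over the 28 pairs of libraries of 1 tissue and 0.657 over the 378 pairs of libraries of different tissues. The difference of 0.208 had p = 1e-05 in a one-sided permutation test of the tissue labels, the smallest p that 100000 shuffles can give. Blood libraries were the most alike, with a mean r of 0.941, followed by skin at 0.921 and heart at 0.915, while lung libraries were the least alike at 0.755. For 28 of the 29 libraries the nearest library was of the same tissue. The exception was ovary replicate 1, whose r was 0.796 with kidney replicate 1 and 0.791 with ovary replicate 3. Between tissues, skin and spleen had the highest mean r, 0.735, and blood and ovary were among the lowest, at 0.577. Genes are not independent replicates, so these r describe pairs of libraries only.

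**Figure D1:**
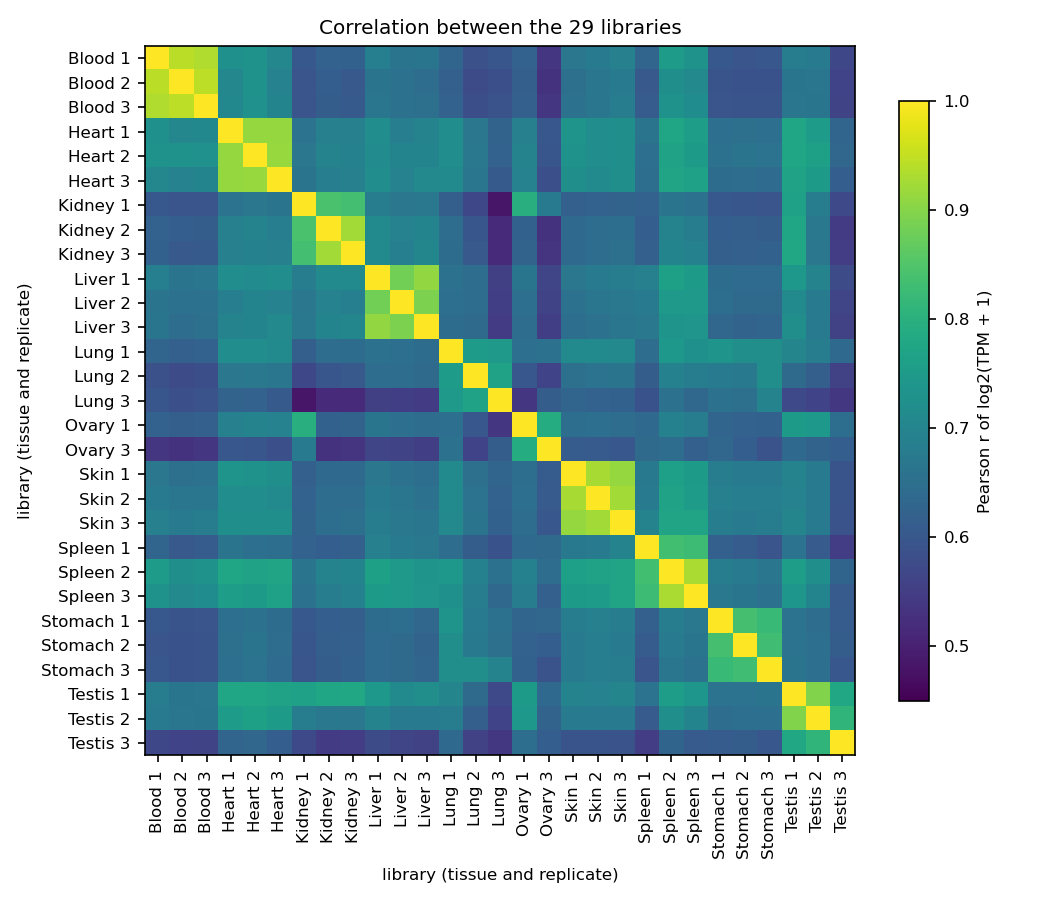
Pearson r of log2(TPM + 1) across genes between every pair of the 29 libraries, with libraries on both axes and r as colour. Blocks of high r follow the tissues, and ovary replicate 1 with kidney replicate 1 stands out between tissues at 0.796.

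Many genes reached a mean of 1 TPM in every tissue, and others in 1 tissue. Of the 53113 genes, 16947 (31.9%) had a mean of 1 TPM or more in all 10 tissues and 10496 (19.8%) in 1 tissue. The tau index, which is 0 for a gene equal in all tissues and 1 for a gene found in 1 tissue, was computed for 52681 genes and was 0.85 or more for 14846 (28.2%). Lung held 3708 of these tissue-specific genes, kidney 2736, testis 2653, ovary 1359 and stomach 1028. Skin held 825, liver 824, heart 768, blood 609 and spleen 336. The order depends on the lowest level admitted. With the highest tissue mean at 5 TPM or more, kidney held 2201, testis 1542 and lung 1477. Specific genes took 37.6% ± 7.55 of all TPM in stomach and 26.7% ± 3.17 in skin (SD, n = 3 each), but 0.311% ± 0.038 in blood (SD, n = 3). Of the kidney genes, 2401 (87.8%) were at 1 TPM or more in every kidney library, whereas 147 (3.96%) of the lung genes were so in every lung library. In testis 1043 were, in ovary 670, skin 657, liver 589, heart 523, blood 322, stomach 319 and spleen 146. Specific genes of testis took 2.28% of TPM in testis replicate 1 and 15.8% in testis replicate 3. Leaving out testis replicate 3 brought the testis number to 1544, and leaving out ovary replicate 3 brought the ovary number to 901. No test was applied to tau.

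**Figure D2:**
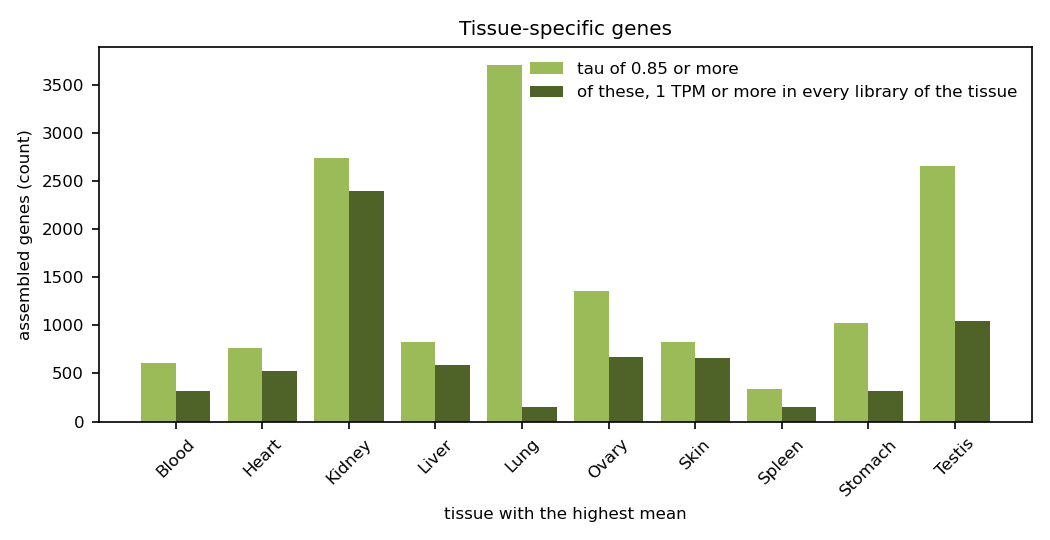
Number of assembled genes with tau of 0.85 or more, by the tissue with the highest mean (light bars), and those of them at 1 TPM or more in every library of that tissue (dark bars). The bars differ most in lung, 3708 against 147, and little in kidney, 2736 against 2401.

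Each tissue was then compared with the mean of the other 9, which asks what sets its expression apart. In limma, 50365 genes at 1 TPM or more in at least 2 libraries were tested, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 with a log2 difference of 1 or more. In all, 35101 genes (69.7%) were called higher in at least 1 tissue, and 12279 were called in none. Differences are on the log2(TPM + 1) scale, which understates changes of low genes. Libraries lying wholly above or below all others were counted over all 50365 tested genes, called or not. Chance gives at most 0.0274% of genes per direction for a tissue of 3 libraries and 0.246% for ovary. The share lying below was 6.59% in blood, 1.18% in stomach, 0.218% in spleen, 0.183% in liver, 0.060% in skin, 0.046% in lung, 0.030% in heart, 0.012% in testis, 0.002% in kidney and 0.246% in ovary. It was thus under that upper limit of chance in testis and kidney and equal to it in ovary. A gene listed at 0 in any other library cannot lie below. TPM is a share of the library, so genes that take a large part of it lower the values of all others. When each library was rescaled by the median of ratios, the median of the genes at 1 TPM or more in every library moved by -0.57 in testis, -0.42 in ovary, -0.35 in kidney, 0.39 in spleen and 0.44 in stomach (log2). Splits of higher against lower calls that moved by more than 10 points with it are given for each tissue.

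**Figure D3:**
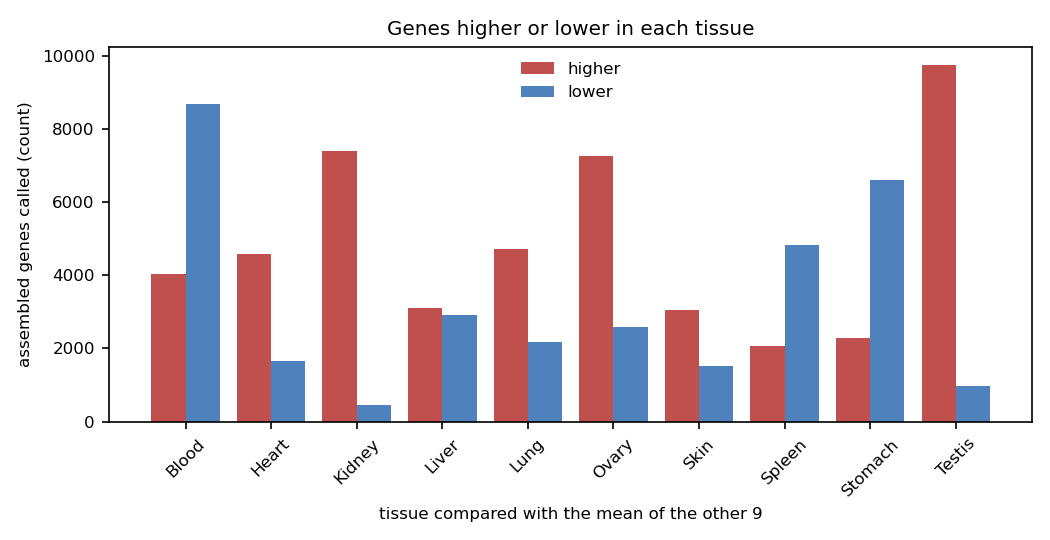
Assembled genes called higher (red) or lower (blue) by limma in each tissue against the mean of the other 9, as counts from 0. In TPM as deposited, testis had the most genes higher, 9745, and blood the most lower, 8680. After rescaling, lung had 5670 higher, close to blood with 5621, ovary with 5515 and kidney with 5445.

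Kidney differed from the other tissues almost wholly by genes that were higher: 7401 were higher and 451 lower, so 94.3% of the calls were higher. All 3 kidney libraries lay above all 26 others for 2896 genes (5.75%). TRINITY_DN49458_c0_g1 averaged 3707 ± 1261 TPM in kidney (SD, n = 3), and the highest other library, testis replicate 1, held 209 TPM. Its log2 difference was 11.27 ± 0.87 (SE; limma, Benjamini-Hochberg adjusted p = 2.19e-10). TRINITY_DN56075_c0_g1 averaged 1137 ± 149 TPM in kidney (SD, n = 3) and 41.2 TPM in testis replicate 1. Kidney replicate 1 also carried genes restricted to ovary and testis replicate 1 carried genes restricted to kidney. Without these libraries and liver replicate 2, 6436 genes were higher in kidney. Leaving out kidney replicate 3 alone gave 6082, so the lower number does not measure what the carried genes contributed. Rescaling gave 5445 higher and 727 lower genes, so 88.2% of the calls were higher. With a pseudocount of 0.1 the lower genes numbered 741.

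Testis had 9745 genes higher, the most of the 10 tissues in TPM as deposited, and 957 lower. Its 3 libraries lay above all others for 2642 genes (5.25%). TRINITY_DN39787_c0_g2 averaged 2782 ± 743 TPM in testis (SD, n = 3) and at most 4.14 TPM in any other library, which was ovary replicate 1. The log2 difference of this gene was 11.03 ± 0.20 (SE; limma, Benjamini-Hochberg adjusted p = 3.04e-20). TRINITY_DN68598_c0_g1 ranged from 4779 to 51394 TPM over the testis libraries and was at most 3.26 TPM elsewhere. Without kidney replicate 1, testis replicate 1 and liver replicate 2, 8936 genes were higher in testis and 1500 lower. After rescaling, 5071 were higher and 1907 lower, a share of higher calls of 72.7% in place of 91.1%. Lung, blood, ovary and kidney then had more genes higher, at 5670, 5621, 5515 and 5445. The lower genes numbered 619 without testis replicate 2 and 567 without testis replicate 3.

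Ovary, with 2 libraries, had 7244 genes higher and 2581 lower, and both libraries lay above the 27 others for 2724 genes (5.41%). TRINITY_DN31514_c0_g1 was at 6560 and 21687 TPM in the ovary libraries. The highest other library was kidney replicate 1 at 2042 TPM, and without kidney replicate 1, testis replicate 1 and liver replicate 2 the highest was 21.1 TPM. Its log2 difference was 12.28 ± 1.32 (SE; limma, Benjamini-Hochberg adjusted p = 4.88e-07). TRINITY_DN4662_c0_g3 averaged 2881 ± 1887 TPM in ovary (SD, n = 2) and was at 804 TPM in kidney replicate 1. Rescaling gave 5515 higher and 5050 lower, so the share of higher calls went from 73.7% to 52.2%. Genes lower in ovary numbered 965 without ovary replicate 3 and 3913 without ovary replicate 1.

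Blood was set apart more by genes that were lower: 8680 were lower and 4026 higher. Blood libraries lay below all 26 others for 3318 genes and above them for 1355. TRINITY_DN431_c4_g7 averaged 8298 ± 2361 TPM in blood (SD, n = 3), and the highest other library, heart replicate 2, held 1401 TPM. This log2 difference was 6.18 ± 0.73 (SE; limma, Benjamini-Hochberg adjusted p = 6.42e-07). TRINITY_DN3806_c0_g1 averaged 578 ± 287 TPM in blood (SD, n = 3) and at most 60.5 TPM elsewhere, in lung replicate 3. Rescaling took the share of higher calls from 31.7% to 42.4%.

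Spleen had 2057 genes higher and 4819 lower. The spleen libraries lay above all others for 330 genes. TRINITY_DN6820_c0_g1 averaged 23489 ± 10273 TPM in spleen (SD, n = 3). Liver replicate 2 held 3583 TPM of it, and without kidney replicate 1, testis replicate 1 and liver replicate 2 the highest other library held 35.8 TPM. For this gene the log2 difference was 12.23 ± 1.13 (SE; limma, Benjamini-Hochberg adjusted p = 7.76e-08). TRINITY_DN23449_c0_g1 averaged 11290 ± 4289 TPM in spleen (SD, n = 3) and was at 690 TPM in liver replicate 2. Without spleen replicate 1 the larger side turned, with 2384 genes higher and 1483 lower. Rescaling left 2954 lower genes and took the share of higher calls from 29.9% to 51.0%.

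Liver had nearly equal numbers of genes higher, 3101, and lower, 2904, and its libraries lay above all others for 988 genes. TRINITY_DN24963_c0_g1 averaged 45236 ± 20772 TPM in liver (SD, n = 3) and at most 469 TPM elsewhere, in lung replicate 2. In limma its log2 difference was 13.52 ± 1.19 (SE; Benjamini-Hochberg adjusted p = 8.73e-09). TRINITY_DN17169_c0_g1 averaged 7672 ± 2962 TPM in liver (SD, n = 3), with 40.7 TPM in lung replicate 2. Liver replicate 2 also carried genes restricted to spleen, and 3011 genes were higher and 2355 lower in liver without it, kidney replicate 1 and testis replicate 1. The lower genes numbered 1932 without liver replicate 2 and 1767 without liver replicate 3. Rescaling took the share of higher calls from 51.6% to 66.1%, and a pseudocount of 0.1 turned the larger side, with 3203 higher and 4411 lower. The larger side also turned without spleen replicate 1, with 3119 higher and 3409 lower, and without ovary replicate 3.

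Heart had 4564 genes higher and 1659 lower, and its libraries lay above all others for 1361 genes. TRINITY_DN18340_c0_g2 averaged 3011 ± 1050 TPM in heart (SD, n = 3) and at most 46.0 TPM elsewhere, in lung replicate 2. That gene had a log2 difference of 10.99 ± 0.61 (SE; limma, Benjamini-Hochberg adjusted p = 2.37e-12). TRINITY_DN4771_c0_g1 averaged 3837 ± 532 TPM in heart (SD, n = 3) and at most 65.2 TPM elsewhere. Without heart replicate 2 the lower genes numbered 1048.

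Stomach had 2268 genes higher and 6611 lower. A few genes dominated it: TRINITY_DN7584_c0_g1 averaged 107025 ± 32132 TPM and TRINITY_DN11110_c1_g1 63633 ± 20979 TPM (SD, n = 3 each). Elsewhere they reached at most 500.2 and 236 TPM, both in lung replicate 3. The log2 difference of the former was 15.37 ± 0.81 (SE; limma, Benjamini-Hochberg adjusted p = 1.31e-12). Stomach libraries lay above all others for 587 genes and below them for 594. Lower genes numbered 4325 without stomach replicate 1 and 3817 without stomach replicate 2. Rescaling gave 3567 higher and 4220 lower genes, with the share of higher calls going from 25.5% to 45.8%.

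Lung had 4715 genes higher and 2181 lower, but its libraries lay above all others for only 340 genes. Among these, TRINITY_DN1855_c0_g2 averaged 17508 ± 2465 TPM in lung (SD, n = 3) and at most 4.81 TPM in any other library, which was stomach replicate 3. The log2 difference for it was 13.41 ± 0.29 (SE; limma, Benjamini-Hochberg adjusted p = 6.14e-19). TRINITY_DN4955_c3_g1 averaged 9555 ± 6082 TPM in lung (SD, n = 3) and at most 5.06 TPM elsewhere. Lower genes in lung numbered 1376 without lung replicate 1 and 1043 without lung replicate 3.

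Skin had 3060 genes higher and 1530 lower, and its libraries lay above all others for 1066 genes. TRINITY_DN29415_c0_g2 averaged 87222 ± 45423 TPM in skin (SD, n = 3), and the highest other library, spleen replicate 1, held 898 TPM. TRINITY_DN709_c19_g2 averaged 26759 ± 5050 TPM (SD, n = 3) and at most 86.8 TPM elsewhere. Its log2 difference of 13.40 ± 0.20 (SE) had a Benjamini-Hochberg adjusted p = 3.47e-22 in limma. The lower genes numbered 1005 without skin replicate 1, 810 without skin replicate 2 and 811 without skin replicate 3.

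The gonads were compared directly. Testis had 7190 genes higher than ovary and 4023 lower. Over all tested genes, the testis libraries lay wholly above those of ovary for 22.8% and wholly below for 11.3%. Chance gives at most 10% per direction, and less where libraries of both are tied at 0. TRINITY_DN57406_c0_g1 averaged 2629 TPM in testis, with a range of 700.2 to 6207 TPM, and was at most 2.45 TPM in ovary. In limma this log2 difference was 9.77 ± 0.59 (SE; Benjamini-Hochberg adjusted p = 5.73e-11). In the other direction, TRINITY_DN31514_c0_g1 averaged 1.35 ± 0.703 TPM in testis (SD, n = 3) against 14123 ± 10696 TPM in ovary (SD, n = 2). Without testis replicate 1, kidney replicate 1 and liver replicate 2, 6013 genes were higher in testis. The larger side turned without ovary replicate 3, with 3518 genes higher in testis and 4009 lower. With only the gonad libraries in the fit, 1093 were higher and 1160 lower.

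Skin and lung, surfaces in contact with the surroundings, were compared because the series concerns adaptation to the environment. Skin had 3198 genes higher than lung and 4155 lower. Over all tested genes, the skin libraries lay wholly above those of lung for 14.8% and wholly below for 11.5%, where chance gives at most 5% per direction. The skin gene TRINITY_DN709_c19_g2 averaged 0.361 ± 0.178 TPM in lung (SD, n = 3), a log2 difference of 14.25 ± 0.27 (SE; limma, Benjamini-Hochberg adjusted p = 5.29e-20). The lung gene TRINITY_DN1855_c0_g2 averaged 0.306 ± 0.073 TPM in skin (SD, n = 3). The larger side turned without lung replicate 3, with 2480 genes higher in skin and 2315 lower. It also turned with only the skin and lung libraries in the fit, with 2746 higher and 1571 lower.

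Blood and spleen, an organ that filters blood, differed by 5065 genes higher in blood and 5030 lower. Over all tested genes, the blood libraries lay wholly above those of spleen for 18.2% and wholly below for 16.1%, where chance gives at most 5% per direction. TRINITY_DN1415_c5_g4 averaged 126 ± 54.8 TPM in blood and 1.83 ± 1.80 TPM in spleen (SD, n = 3 each). TRINITY_DN5667_c0_g1 averaged 20.2 ± 4.51 TPM in blood and 24291 ± 12484 TPM in spleen (SD, n = 3 each). Blood minus spleen, the log2 difference of the latter was -10.07 ± 1.32 (SE; limma, Benjamini-Hochberg adjusted p = 6.16e-06). As a set, genes restricted to spleen read at medians of 0.067% to 0.098% of their spleen mean in the blood libraries. Expression of TRINITY_DN5667_c0_g1 in blood can therefore not be told apart from carried RNA. The near balance did not hold throughout: 2855 genes were higher in blood and 5980 lower without spleen replicate 1, 6256 and 3847 without spleen replicate 2, and 3542 and 4766 without blood replicate 1. With a pseudocount of 0.1, 5230 were higher and 6504 lower.

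Some libraries carried genes restricted to another tissue, taken as genes at 20 TPM or more in every library of the home tissue and below 5% of its mean in the median library of each other tissue, leaving out the tissue of the library being read. Of 192 such ovary genes, all 192 were at 1 TPM or more in kidney replicate 1, at a median of 44.0% of their ovary mean. These ovary genes summed to 3.96% of TPM in kidney replicate 1, 0.029% in kidney replicate 2 and 0.039% in kidney replicate 3. Of 388 kidney genes, 366 (94.3%) were at 1 TPM or more in testis replicate 1, at a median of 7.58% of the kidney mean. Of 53 spleen genes, 49 (92.5%) were so in liver replicate 2, at a median of 8.68%. Of 114 heart genes, 81, 72 and 72 were at 1 TPM or more in skin replicates 1, 2 and 3, and their medians over the 114 were 9.66%, 5.21% and 3.27%. The heart lists read in the other tissues held 56 to 65 genes. The longer list for skin thus includes genes at 5% or more of the heart mean in the median skin library. For these, expression shared by heart and skin cannot be told apart from carried RNA. In lung replicate 2, 65 heart genes were at a median of 2.29% and 188 liver genes at a median of 0.677%. Of the liver genes, 65.4% were at 1 TPM or more there, against 18.1% in lung replicate 1 and 15.4% in lung replicate 3. Of 108 stomach genes, 63.0% were so in lung replicate 3, 48.1% in lung replicate 2 and 32.4% in lung replicate 1. The stomach lists read in the other tissues held 89 to 103 genes. That for lung thus includes some genes at 5% or more of the stomach mean in the median lung library. No lung library was among those left out together. At far lower levels, spleen genes were read in every library of blood (medians 0.098%, 0.095% and 0.067%) and skin (0.122%, 0.136% and 0.178%). Skin genes were read so in blood (0.135%, 0.112% and 0.091%) and spleen (0.142%, 0.194% and 0.168%). Apart from liver replicate 2, the highest median in the other tissues was 0.016% for spleen genes and 0.02% for skin genes. The source was not tested. Blood had few such genes: all 7 read in heart were at 1 TPM or more in heart replicate 2. Their median there was 16.9%, against 2.85% in heart replicate 1 and 5.41% in heart replicate 3. The blood lists read in the other tissues held 2 or 3 genes. Most of the 7 thus entered because they were at 5% or more of the blood mean in the median heart library. Their presence in heart is therefore partly built into the choice.

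**Figure D4:**
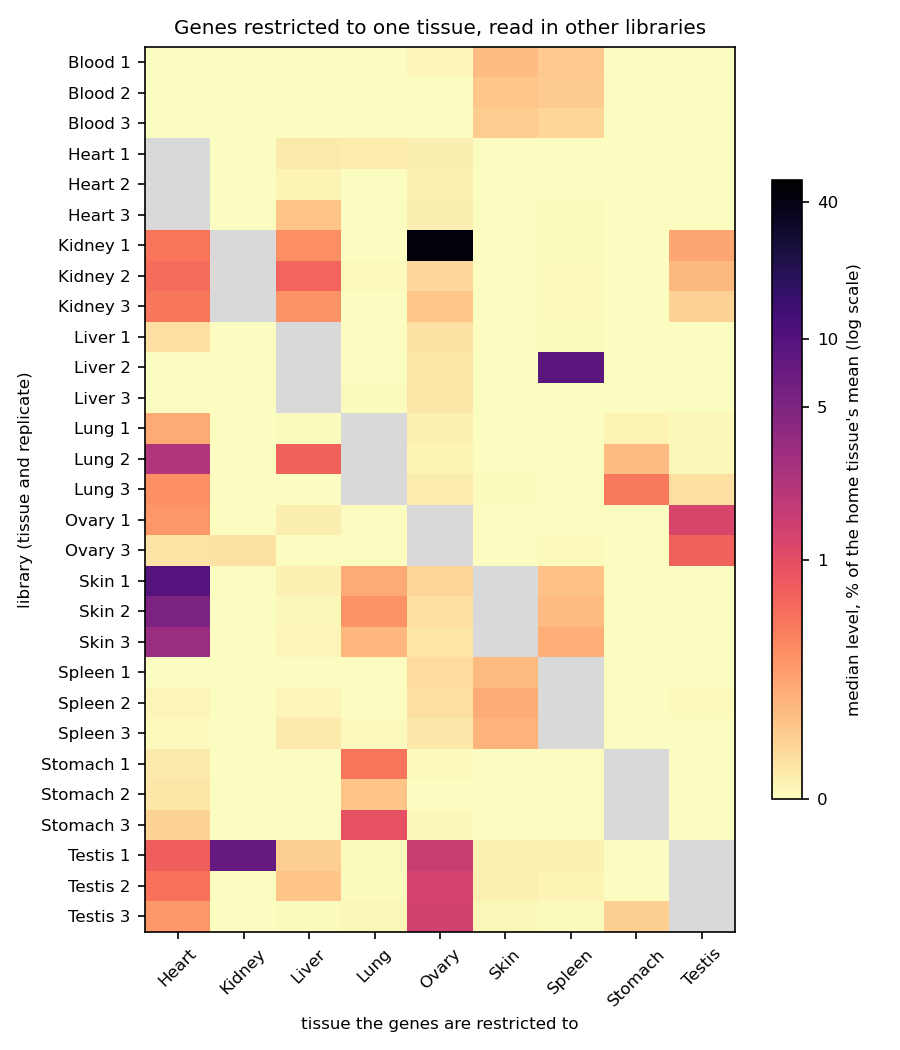
Genes restricted to 1 tissue (horizontal axis) read in each library (vertical axis), coloured on a log scale by their median level as a percent of the home tissue's mean; grey marks the home tissue's own libraries, and genes of blood are not drawn. Kidney replicate 1 reads 44.0% for ovary genes, liver replicate 2 reads 8.68% for spleen genes and testis replicate 1 reads 7.58% for kidney genes.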

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

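Leaving out kidney replicate 1, testis replicate 1 and liver replicate 2 together, and requiring tau genes in every library of their tissue, were chosen after seeing the data. All 266 alternatives of the 32 named gene results kept their direction and stayed within the adjusted p limit. These genes were chosen from the same data for the largest differences, so this says little about other genes. For them, dropping the filter and leaving out single libraries of other tissues were not tried. No filter on low values (27 results), Spearman correlation (1) and the replicate number as a block (26) moved no count by more than 1.5 times. The block gave 3974 genes higher in blood and 9700 in testis. The labels do not say that replicate numbers pair libraries, and in 0 of 45 tissue pairs was every r over 0.1 between same-numbered deviations from tissue means (range -0.18 to 0.241). As a hint that numbers share something, 21 of 29 libraries lay closest to their own number, against a mean of 9.67 in 100000 shuffles within tissues (one-sided permutation p = 0.00203). The cause was not tested for the changes that follow, unless fewer libraries or genes entered by construction. A pseudocount of 0.1 gave 741 genes lower in kidney and 4411 in liver. Rescaled TPM gave 727 lower in kidney, 5050 in ovary, 2954 in spleen, 4220 in stomach and 1907 in testis, with 3567 higher in stomach and 5071 in testis. With only the libraries of both tissues in the fit, testis against ovary gave 1093 higher and 1160 lower, and skin against lung 1571 lower. The 3 libraries left out together gave 1500 lower in testis and changed none of the other 27 results by that much. Tau gave 9274 genes at 0.95 or more, 22320 without the log, 9097 at 5 TPM or more and 6817 present in every library of the tissue.

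Of 812 values with 1 library left out, 18 moved by more than 1.5 times. All 18 left out a library of the tissue or pair that the result names. Most of the 812 left out a library of another tissue, which can change the result little. Lower genes ranged from 1048 to 1791 in heart, 1767 to 3409 in liver, 1043 to 3156 in lung, 965 to 3913 in ovary, 810 to 1923 in skin, 1483 to 6890 in spleen, 3817 to 7761 in stomach and 567 to 1340 in testis. Skin against lung ranged from 2315 to 4438 lower, blood against spleen from 2855 to 6256 higher, and testis against ovary from 3518 to 9528 higher. With an ovary library left out, the lone one is assumed to vary like the other tissues. List tests and sums by gene symbol were not run, since the table pairs no names with IDs. Depth is unknown, so what it limits was not measured.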

Other observations

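Of the tests below with a prediction, that of exchanged labels between kidney replicate 1 and ovary replicate 1 was chosen only after the result was seen, as were leaving out 3 libraries and reading kidney genes without testis replicate 1. Some genes were shared by 2 tissues, taken as the lower of both means at 5 TPM or more and at least 5 times the next tissue. Over the 45 pairs of tissues there were 694 such genes, and 9353 genes stood out in 1 tissue by the same limits. Kidney and liver shared 108, heart and skin 92, and lung and stomach 54. Kidney and ovary shared 115 and ovary and testis 56, and without kidney replicate 1, testis replicate 1 and liver replicate 2 these were 11 and 189. Blood and spleen shared 0.

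The 10 most abundant genes of blood took 50.8% ± 5.12 of TPM in blood, 22.0% ± 11.2 in lung, 18.4% ± 7.77 in heart and 16.7% ± 1.51 in kidney, against 5.83% ± 0.873 in skin (SD, n = 3 each). They are not restricted to blood, so these shares do not measure blood content. TRINITY_DN132001_c0_g1 is among them and alone averaged 10.8% in lung, 7.78% in heart and 8.09% in kidney. Its lowest tissue mean was 2.48%. Genes at 5 TPM or more in 1 library and at most 5% of that level in every other numbered 521 in lung replicate 3, 470 in testis replicate 3, 247 in lung replicate 2 and 209 in ovary replicate 3, with a median of 24 over the libraries.

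Chance is argued against for the tissue labels taken as a whole. For each of the 9 tissues with 3 libraries, only 1 of 100 splits of the 29 libraries, the real one, gave as many calls. Each shuffle moved the labels of all tissues together, which also raised the spread within groups. The splits therefore cannot test the grouping of a single tissue apart from the others. The real count and the highest of the other splits were 12706 and 1867 for blood, 6223 and 2581 for heart, 7852 and 2186 for kidney, 6005 and 3932 for liver and 6896 and 3319 for lung. They were 4590 and 2323 for skin, 6876 and 3294 for spleen, 8879 and 2936 for stomach and 10702 and 3280 for testis. The 10 splits of skin against lung (7353, highest other 1752) and of blood against spleen (10095, highest other 3) are too few for a share under 0.05. Splits were not counted for the ovary comparisons, with 2 libraries.

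Genes restricted to ovary were in kidney replicate 1 at levels that followed ovary replicate 1 (r = 0.953 across 192 genes, which are not independent) more closely than ovary replicate 3 (r = 0.714). An exchange of labels with ovary replicate 1 is argued against, since 5 of 383 kidney genes (1.3%) were at 1 TPM or more there. Ovary played no part in the choice of those genes. The test set for this gave 1.57%, which cannot decide, as its 699 kidney genes were chosen as low in the ovary median. Ovarian tissue or RNA in the library may be the source, and it cannot be told apart from other sources here: kidney genes had a median ratio to kidney replicate 3 of 0.912 over 699 genes, against 0.659 with kidney replicate 2 as the reference, and the ratio between those references was itself 1.37. That spread keeps open whether kidney RNA was diluted. Biological differences between the animals, whose sex the labels do not give for kidney, were not tested.

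Genes restricted to kidney in testis replicate 1 may come from kidney tissue or RNA, as their levels followed the kidney mean across 388 genes with r = 0.811, against 0.127 in testis replicate 2 and 0.141 in testis replicate 3. A kidney library under a testis label is argued against, since 99.2% of 132 testis genes were at 1 TPM or more in it. How such RNA would have entered was not tested, nor was a biological explanation.

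Lung-specific genes were mostly missing from part of the lung libraries: 1729 were at 1 TPM or more in replicates 2 and 3 alone, 897 in replicate 3 alone and 147 in all 3. Low levels and sampling are argued against as the whole cause, since 13.2% of the 569 genes with a mean of 10 TPM or more were in all 3, against 99.6% of 1346 such kidney genes. Reads from another organism cannot be told apart from host genes here: the share of the missing genes listed at 0 in all 26 other libraries was 2.40 times that of kidney genes matched in level, but 0.765 times without testis replicate 1, which carries kidney genes. The share was 32.1% for these lung genes and 6.80% for the 147 in all 3 lung libraries, while specific genes missing from part of their own libraries had 21% in stomach and 53.4% in kidney. A host cell type or tissue present in some lung samples, or biological differences between them, stay open as untested, and no sequences were used here.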
